A study of Mus musculus with 7 samples.

How the data were processed

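Polyadenylated RNA from dissected adult mouse hippocampus was sequenced as 7 libraries, prepared per the labels with the Qiagen RNeasy Plus kit and the Illumina TruSeq mRNA protocol. There were 3 libraries of wild-type Ammon's horn, 3 of Ammon's horn from mice homozygous for a deletion of Khdrbs3, and 1 of wild-type dentate gyrus. Per the labels, the null allele had been crossed back to C57Bl6 for 8 generations. The labels do not say whether each library came from a separate animal, so gene and exon-bin p-values measure the spread between these libraries. Tests of gene lists also depend on the correlation between genes, and tests of genes near Khdrbs3 count genes without using that spread.

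The authors deposited raw counts in 2 forms. The first is a table of counts for 38924 gene records, 22572 of them protein coding, counted from the first to the last base of each gene with introns included. The second is 1 file per library with counts in 359565 exon bins, the non-overlapping pieces into which DEXSeq divides the exons of 37718 genes; 940 of these are groups of overlapping genes joined into 1. The authors' processing notes name Trim Galore 0.3.5, TopHat2 2.0.8b, bedtools 2.17.0, DESeq2 1.0.19 and the mm10 genome, without saying what each was used for. The gene identifiers carry the versions of GENCODE release M2. Neither form had been normalised. In 14488 genes with at least 700 counts, the gene-table count was a median of 1.60 times the sum of the exon bins. Reads lying in no bin were at most 4.83% of those in the exon-bin files. The cause of the ratio was not tested, and the 2 forms need not count reads in the same way.

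The gene table summed to between 50230733 and 67692326 counts per library and the exon bins to between 29698245 and 39904606. Of the reads in the exon-bin files, between 1.73% and 2.01% were set aside as ambiguous and between 3.52% and 4.83% as lying in no bin. Shares of reads in a single library are given with exact 95% Clopper-Pearson intervals, and these cover counting error only.

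Gene counts were tested in R 4.3.3 with edgeR 4.0.16 by the quasi-likelihood F test, after TMM normalisation and edgeR's own low-count filter. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The knockout comparison used the 6 Ammon's horn libraries. The dentate gyrus comparison used all 7 libraries in 3 groups with 1 common estimate of the spread, and counts by direction were kept to changes of at least 2-fold. Because there is only 1 dentate gyrus library, it had no replicate and was assumed to vary like the Ammon's horn libraries. Levels are TMM-scaled CPM, and the error of a log2 fold change is its standard error. The spread between libraries of a group, as a biological coefficient of variation, was 10.6% in the knockout fit and 10.8% in the 3-group fit.

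Exon usage was tested with edgeR's diffSpliceDGE, which compares the change of a bin with the change of its whole gene. Bins with at least 10 reads in at least 3 libraries were tested in genes with at least 2 such bins. Genes were called by the Simes method. The share of a bin is its percentage of all exon-bin reads of the gene. Bin coordinates were taken from GENCODE release M21 gene models on the same genome build, for 16230 models of the same version and 10013 of 19444 models of another version whose bin number and gene ends could be rebuilt. Bins of other genes are named by number alone.

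Lists of genes were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01, again with an estimated correlation, and with fry. The 28 lists were the KHDRBS family, known or reported KHDRBS3 splicing targets, other neuronal RNA-binding and splicing regulators, neurexin ligands and synaptic adhesion, ionotropic glutamate receptors, GABA-A receptor subunits, synaptic vesicle exocytosis, activity-regulated early genes, heat shock and stress, mitochondrially encoded genes, sex-specific genes, cholesterol synthesis, oxidative phosphorylation, and markers of interneurons, CA1 pyramidal cells, CA2 and CA3 pyramidal cells, dentate granule cells, adult neurogenesis, mossy cells, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, endothelial and mural cells, choroid plexus, ependyma, thalamus and habenula, and neocortex and subiculum. Elavl2, Grik4, Nxph1, Stxbp5l and Stxbp6 each stand in more than 1 list. The tests, the thresholds, the lists and the rule for naming genes were fixed before the data were examined.

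The rule named the KHDRBS family, the 12 genes with the largest log2 fold change in each direction among those called, and called members of the lists. In the knockout their 3 and 3 libraries also had to be free of overlap, and in the dentate gyrus their mean had to reach 5 CPM over the wild-type libraries, with up to 4 members of each list as examples. For exon usage it named up to 20 called genes in the knockout, 12 in the dentate gyrus, and each gene of the splicing-target list by its bin of smallest p. Some genes that the rule names are not reported here. Genes called within 10 Mb of Khdrbs3 were counted against the rest with a two-sided Fisher's exact test.

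The tests were tried on simulated counts with the depth and spread of these libraries. Changed genes were drawn from those with at least 1 CPM. Changed bins were drawn from those with a mean of at least 50 reads that made up a minor part of their gene. Recovery of changes in lower genes and bins, which the real tests include, was not measured. With 50 genes changed by each of 1.25-fold, 1.5-fold, 2-fold and 4-fold in the knockout design, 16%, 72%, 94% and 100% were recovered, and 21 of 162 calls were false. In the dentate gyrus design 34.3% and 82.1% were recovered at 1.5-fold and 2-fold. For exon bins 50.7% and 91.0% were recovered at these folds in the knockout design, and 26.9% and 74.6% in the dentate gyrus design.

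The alternatives were DESeq2 1.42.0, limma-voom, other scaling factors (RLE), looser and stricter filters, sums of exon bins as gene counts, other sets of libraries in the fit, and leaving out each library in turn. Fits without mitochondrial genes, with the choroid plexus marker level as a covariate, or without both choroid-rich knockout libraries, and a count without Khdrbs3 itself, were chosen after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.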

Results

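The dataset holds RNA-seq of the Ammon's horn (the CA fields of the hippocampus) of wild-type mice (n = 3 libraries) and of mice lacking Khdrbs3 (n = 3 libraries), and of 1 wild-type dentate gyrus. Khdrbs3 encodes KHDRBS3, also called T-STAR or SLM2, an RNA-binding regulator of alternative splicing that is abundant in brain. Wild-type Ammon's horn libraries held 53357003, 67692326 and 60556455 gene counts, knockout libraries 61204108, 64007879 and 50230733, and the dentate gyrus library 58527330. Mitochondrial genes took 10.6%, 10.9% and 10.4% of the counts in wild-type Ammon's horn, 13.4%, 14.1% and 11.1% in the knockout, and 9.87% in the dentate gyrus. On a principal component analysis of log2 CPM, the first component (31.5% of the variance) set the dentate gyrus library apart from the 6 Ammon's horn libraries.

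The deleted gene was examined first. Reads of Khdrbs3 (ENSMUSG00000022332.7, mm10 chromosome 15, 68928420 to 69093512) were almost absent from its second exon bin in the knockout. That bin spans 119 bp, from 68995052 to 68995170, and every one of the 6 annotated transcripts holds it. It took 11.4% ± 0.32 (SD, n = 3) of the gene's exon reads in wild-type Ammon's horn and 0.0678% ± 0.0117 (SD, n = 3) in the knockout. Wild-type libraries had 808, 1103 and 964 reads there, and knockout libraries 6, 9 and 7. In the dentate gyrus the share was 11.0% (95% interval 10.1 to 11.9%, 506 reads). Reads in the rest of the gene did not fall: bin 3 was 1.03-fold and bins 4 to 9 between 1.40-fold and 1.78-fold of the wild-type CPM. The gene as a whole rose from 138 ± 4.28 to 197 ± 3.08 CPM (SD, n = 3 each), a log2 fold change of 0.51 (SE 0.05, edgeR adjusted p = 0.0025).

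**Figure D1:**
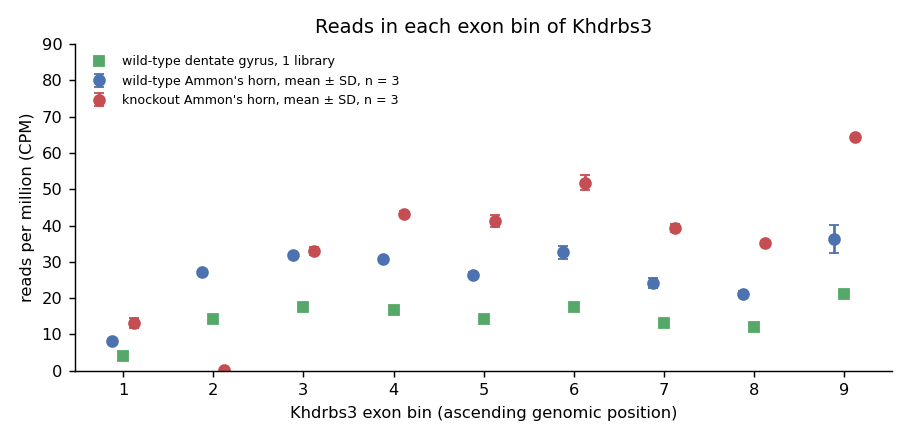
Reads in each exon bin of Khdrbs3 (CPM, vertical axis, from 0) by bin number (horizontal axis), as mean ± SD of 3 libraries for wild-type and knockout Ammon's horn and as 1 library for the dentate gyrus. In the knockout, bin 2 lies at 0.00802-fold of the wild-type level and bin 9 at 1.78-fold.

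The knockout comparison asks which transcripts change in Ammon's horn when Khdrbs3 is deleted. Both paralogs of the gene rose. Khdrbs2 (SLM1, chromosome 1, 32172806 to 32657738) went from 11.3 ± 1.29 to 20.4 ± 0.92 CPM (SD, n = 3 each), a 1.81-fold rise (log2 fold change 0.86, SE 0.09, edgeR adjusted p = 0.0054). Khdrbs1 (Sam68, chromosome 4, 129703164 to 129742303) went from 84.9 ± 0.33 to 121 ± 2.66 CPM, a 1.43-fold rise (log2 fold change 0.51, SE 0.05, edgeR adjusted p = 0.0017). Counted over exons alone, Khdrbs2 rose from 4.38 ± 0.54 to 19.6 ± 1.01 CPM (log2 fold change 2.16, SE 0.11, adjusted p = 2.4e-06) and Khdrbs1 by a log2 fold change of 0.52 (SE 0.05). All 3 members of the KHDRBS family rose, over all genes and adjusted over the list alone, and the direction was the same with RLE scaling and with exon-bin sums. The family was called by camera (adjusted p = 1.4e-07), but not with an estimated correlation (camera adjusted p = 0.1395). The list holds the deleted gene itself and its paralogs, each already called, so this test adds nothing beyond the single genes.

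**Figure D2:**
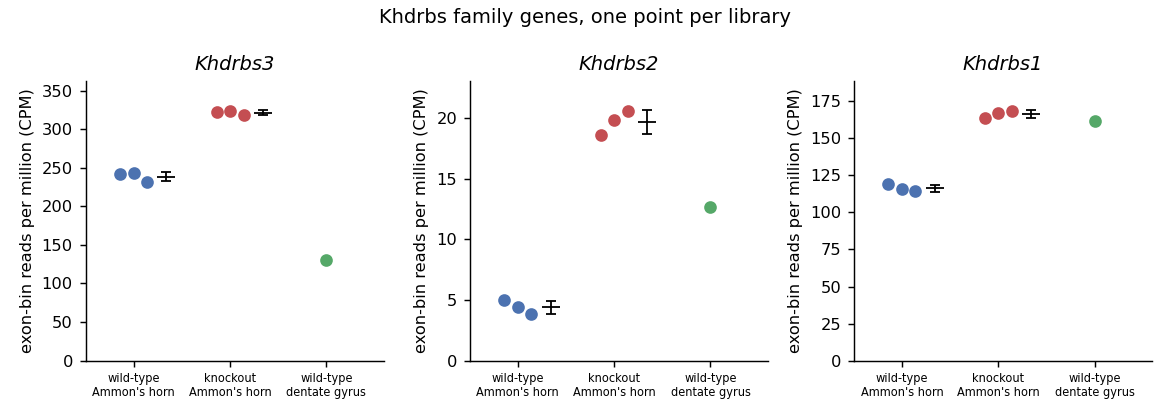
Levels of Khdrbs1, Khdrbs2 and Khdrbs3 from exon-bin sums (CPM, vertical axis, from 0) in wild-type Ammon's horn, knockout Ammon's horn and dentate gyrus, with a point per library and mean ± SD bars. Khdrbs2 lies between 18.6 and 20.6 CPM in the knockout libraries, between 3.87 and 4.96 in wild-type Ammon's horn, and at 12.6 in the dentate gyrus.

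Of 22830 genes tested, 15 were higher and 2 lower in the knockout, and 1914 (8.38%) had an unadjusted p under 0.05. Outside the family, the called nuclear genes that were higher were Slc16a8, a monocarboxylate transporter (log2 fold change 1.91, SE 0.27, 0.330 to 1.23 CPM), Card10, a signalling scaffold of the NF-kappaB pathway (1.27, SE 0.18, 5.62 to 13.5 CPM), the pseudogenes Gm12816 (0.69, SE 0.10) and Rpl3-ps1 (0.65, SE 0.09), and Mc2r, the corticotropin receptor (0.51, SE 0.07). Mc2r lay outside the naming rule and is given because its values were seen. The 2 lower genes were H2-Q2, a class I histocompatibility gene, which fell by 2.12 on the log2 scale (SE 0.20, 2.53 to 0.579 CPM, edgeR adjusted p = 0.0022), and Cldn11, a tight junction protein of myelin, which fell by 0.34 (SE 0.05, 86.3 to 68.2 CPM, edgeR adjusted p = 0.0457).

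The other 7 called genes are mitochondrial. The tRNA genes mt-Ty, mt-Tq, mt-Tn, mt-Tw and mt-Tl1 were higher by log2 fold changes of 4.72 (SE 0.20), 4.23 (SE 0.34), 3.54 (SE 0.15), 1.83 (SE 0.20) and 1.14 (SE 0.16). The respiratory chain genes mt-Nd2 and mt-Co1 were higher by 0.69 (SE 0.06) and 0.56 (SE 0.08). In the exon-bin sums, the joined bins of mt-Nd2 and mt-Tw were instead lower (log2 fold change -0.57, SE 0.07, adjusted p = 0.0059), as were those of mt-Nd1 and mt-Ti (-0.44, SE 0.05, adjusted p = 0.0079), and mt-Co1 had a value of -0.40 (adjusted p = 0.242). Exon-bin sums gave 8 calls among 15288 tested, 5 of them shared with the gene table: Khdrbs1, Khdrbs2, Khdrbs3, Rpl3-ps1 (2.81, SE 0.19) and Cldn11 (-0.36, SE 0.05). Capn11, a calpain protease, was called there alone (2.74, SE 0.38). Most gene-table reads of Rpl3-ps1 were not in its exon bins. Its wild-type and knockout means were 4.39 and 30.7 CPM in the bins, against 87.7 and 138 in the gene table.

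Of the 17 calls, 9 held whichever of the 6 libraries was left out, 10 held with limma-voom and 17 with DESeq2, which made 73 calls upward and 44 downward. The number of calls was 11 without wild-type replicate 2, 11 without knockout replicate 1, and 55 without knockout replicate 2, which had the lowest level of choroid plexus markers. The number of lower genes was 6 without wild-type replicate 1 and 8 without wild-type replicate 3, and 1 without wild-type replicate 2, knockout replicate 1 or knockout replicate 3. Cldn11 lost its call without any 1 of the 6 libraries (adjusted p up to 0.298), while its log2 fold change stayed between -0.36 and -0.31. Slc16a8 lost its call without each library but knockout replicate 2 (up to 0.274), with values between 1.75 and 2.10. Card10 lost it without each wild-type library or knockout replicate 3 (up to 0.174). Gm12816, Rpl3-ps1 and mt-Co1 lost it without each wild-type library or knockout replicate 1 (up to 0.208, 0.1398 and 0.208), and mt-Tl1 without replicate 1 or 3 of either genotype (up to 0.174). Mc2r was called in 1 of the 6 such fits. With the choroid plexus covariate Slc16a8, Cldn11 and Mc2r lost their calls (edgeR adjusted p = 0.106 and 0.191 for Slc16a8 and Cldn11). Fitted without mitochondrial genes, 4 calls were left: Khdrbs1, Khdrbs2, Khdrbs3 and H2-Q2. In the exon-bin sums H2-Q2, Card10 and Slc16a8 did not pass (log2 fold changes -0.76, 0.77 and 2.26, adjusted p = 0.801, 0.212 and 0.242). Without both choroid-rich knockout libraries only 1 knockout library was left, so only fold changes are given for that fit. Khdrbs1, Khdrbs2, Khdrbs3 and H2-Q2 kept their direction (log2 fold changes 0.50, 0.91, 0.54 and -1.95).

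Oligodendrocyte and microglial markers had mostly negative values in the knockout. Of 14 oligodendrocyte markers 13 had negative values (median log2 fold change -0.18); 1 passed over all genes (Cldn11) and 6 were lower when adjusted over the list alone, and Mbp had a value of -0.23. All 12 microglial markers had negative values (median -0.19), among them Tmem119 (-0.37) and C1qb (-0.27); none passed over all genes and 6 were lower when adjusted over the list alone. Camera called both lists (adjusted p = 8.9e-06 and 4.3e-06). Neither was called with an estimated correlation (adjusted p = 0.298 and 0.1395), while fry called the microglial list (adjusted p = 0.0196) and not the oligodendrocyte list (adjusted p = 0.0701).

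Choroid plexus markers differed between libraries of the same genotype. Ttr, the transthyretin gene of choroid plexus epithelium, stood at 731, 2.84 and 673 CPM in the 3 knockout libraries, at 126, 21.9 and 5.67 in wild-type Ammon's horn and at 222 in the dentate gyrus. All 12 markers had positive values (median log2 fold change 1.67); none passed over all genes and 12 were higher when adjusted over the list alone. Camera called the list (adjusted p = 1.4e-04) but not with an estimated correlation (adjusted p = 0.651).

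The mitochondrially encoded list was called upward (median log2 fold change 0.25, 11 of 13 positive, 2 called over all genes and 4 adjusted over the list alone, adjusted p = 0.0015). With an estimated correlation the adjusted p was 0.651. Without knockout replicate 2 the median was 0.048 and the adjusted p 0.287, without knockout replicate 3 the median was 0.37, and with exon-bin sums it was -0.11. The median was 0.40 with the choroid plexus covariate and 0.50 without both choroid-rich libraries. Nuclear genes of oxidative phosphorylation were called downward, with 20 of 20 values negative (median -0.08, Cox6c -0.20, adjusted p = 1.4e-04), though no member passed over all genes or adjusted over the list alone, and the adjusted p with an estimated correlation was 0.651. Interneuron markers were called upward (15 of 20 positive, median 0.08, adjusted p = 0.0138), with none called over all genes and 1 adjusted over the list alone, Reln (0.18). That call was absent with an estimated correlation (camera adjusted p = 0.651) and with the choroid plexus covariate (median 0.042, camera adjusted p = 0.252). It was also absent without wild-type replicate 2, wild-type replicate 3 or knockout replicate 1 (camera adjusted p up to 0.228, lowest median 0.049, without knockout replicate 1). Without both choroid-rich libraries the median was 0.026.

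None of the 21 other lists was called by camera, the smallest adjusted p being 0.121, and none of their 303 members passed over all genes. Median log2 fold changes were -0.10 for heat shock and stress genes, 0.05 for ionotropic glutamate receptors, 0.02 for GABA-A receptor subunits, 0.02 for synaptic vesicle exocytosis genes and 0.02 for neurexin ligands and adhesion genes. They were 0.03 for other splicing regulators and 0.01 for cholesterol synthesis genes. Known or reported KHDRBS3 splicing targets, whose last 5 genes (Stxbp5l, Enpp2, Dgkb, Kif21a and Cask) the study chose on these samples and so are no independent evidence, had a median of -0.0020. Activity-regulated early genes had a median of 0.03 while the test pointed down (adjusted p = 0.940). Medians of neuronal markers were -0.05 for CA1, -0.02 for CA2 and CA3, -0.0052 for granule cells, -0.07 for adult neurogenesis and 0.05 for mossy cells. Those of other cells and regions were -0.04 for astrocytes, -0.06 for oligodendrocyte precursors, -0.05 for endothelial and mural cells, 0.06 for ependyma, 0.10 for thalamus and habenula and 0.07 for neocortex and subiculum, a list that fry called (adjusted p = 0.0376). The sex-specific list had a median of 0.05. Camera called ionotropic glutamate receptors and heat shock genes without wild-type replicate 3 (adjusted p = 0.0155 and 0.0470) and with limma-voom (0.0410 and 0.0345), ependymal markers without knockout replicate 3 (0.0490), and thalamus and habenula markers without knockout replicate 2 (0.0362). Adjusted over the list alone, Dcx was higher (0.33) and Fibcd1 (-0.24) and Olig1 (-0.17) lower.

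A further question is whether called genes cluster near the targeted locus, since flanking sequence may differ after a backcross. Within 10 Mb of Khdrbs3, 2 of 193 tested genes were called, Khdrbs3 itself and Card10, against 15 of 22637 elsewhere (odds ratio 15.8, two-sided Fisher's exact p = 0.0089). With Khdrbs3 left out of the count, the Fisher's exact p was 0.126. With Khdrbs3 kept in the count, the p was 0.135, 0.0900 and 0.142 without wild-type replicates 1, 2 and 3. It was 0.0793 and 0.112 without knockout replicates 2 and 3 (two-sided Fisher's exact tests). Slc16a8 lies farther off on the same chromosome, at 79251014 to 79254761, and enters a window of 20 Mb, for which the two-sided Fisher's exact p was 0.0030, or 0.0310 without Khdrbs3. Slc16a8 was called in only 1 of the 6 fits with a library left out, the one without knockout replicate 2, and not with the choroid plexus covariate (edgeR adjusted p = 0.106). A window of 5 Mb held Khdrbs3 alone (two-sided Fisher's exact p = 0.0308), so that p rests on the targeted gene. Without Khdrbs3, 0 of 41 tested genes in that window were called.

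Exon usage is the comparison closest to the known role of KHDRBS3. In the knockout, 1 exon bin in each of Nrxn2 and Nrxn3, which encode presynaptic adhesion receptors, was used more. Bin 44 of Nrxn2 (chromosome 19, 6513716 to 6513805) rose from 1.47% ± 0.052 to 5.05% ± 0.16 of the gene's exon reads (SD, n = 3 each), a usage log2 fold change of 1.78 (SE 0.11, edgeR adjusted p = 1.1e-34). Bin 34 of Nrxn3 (chromosome 12, 90199147 to 90199236) rose from 0.843% ± 0.082 to 2.25% ± 0.139 (log2 fold change 1.42, SE 0.16, edgeR adjusted p = 1.5e-11).

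The Nrxn2 and Nrxn3 bins are each a coding exon of 90 bp, which is the length of the exon known as alternatively spliced segment 4 in these genes. Of 8 annotated Nrxn2 transcripts that span the bin, 2 skip it, and of 7 Nrxn3 transcripts 2 skip it. Both bins were higher in every knockout library than in every wild-type library. The gene-level counts of Nrxn2 and Nrxn3 had log2 fold changes of -0.02 and 0.09 and did not pass.

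**Figure D3:**
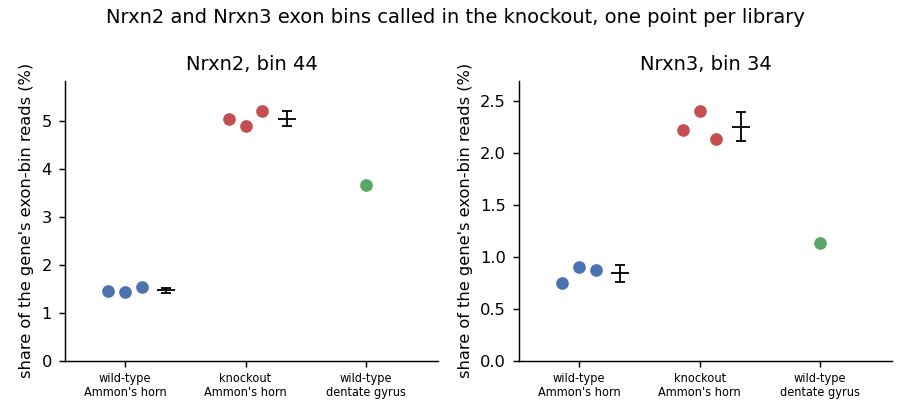
Share of the gene's exon reads (percent, vertical axis, from 0) taken by bin 44 of Nrxn2 and bin 34 of Nrxn3, with a point per library of wild-type Ammon's horn, knockout Ammon's horn and dentate gyrus and mean ± SD bars. In each gene the 3 knockout libraries lie above the 3 wild-type Ammon's horn libraries.

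In all, 5 of 166154 bins in 5 of 12168 genes passed, 4 used more and 1 less, and 2852 bins had an unadjusted p under 0.05. The share of bins under that threshold was below 0.05, the share that would arise with no change in usage. The bin used less is bin 2 of Khdrbs3 (log2 fold change -7.37, SE 0.14). It is not tested without any 1 wild-type library, since too few libraries then reach 10 reads. The bins used more include bin 18 of Apoe, the apolipoprotein E gene, with 148, 135 and 12 reads in the knockout against 6, 14 and 17 in wild-type Ammon's horn (log2 fold change 3.14, SE 0.38, edgeR adjusted p = 1.2e-07). The high counts are in knockout replicates 1 and 2, and the bin was not called with limma-voom (adjusted p = 0.727). The number of bins was 8 without wild-type replicate 2 and 8 without knockout replicate 3, and the number of genes 8 without knockout replicate 1.

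Among 291 bins of the splicing-target genes, 3 were called over all bins, among them those of Nrxn2 and Nrxn3, and 5 when adjusted over the list alone; the genes that the study chose on these samples are no independent evidence. Called over the list alone were bin 10 of Stxbp5l, a syntaxin-binding gene (usage log2 fold change 0.70, SE 0.20, adjusted p over the list alone 0.0472), and bin 11 of Kif21a, a kinesin (0.55, SE 0.16, adjusted p over the list alone 0.0472). Best bins of Cask (-0.76, SE 0.28), Dgkb (-0.39, SE 0.18) and Enpp2 (-1.24, SE 0.79) did not pass either way.

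The dentate gyrus was compared with wild-type Ammon's horn to place these transcripts across hippocampal regions. Genes of dentate granule cells were higher in the dentate gyrus and genes of CA1 pyramidal cells lower. Prox1, a homeobox regulator of granule cell identity, stood at 210 CPM against 23.6 ± 4.53 (SD, n = 3; log2 fold change 3.15, SE 0.18), and C1ql2 at 149 against 16.4 ± 2.21 (3.18, SE 0.18). Fibcd1, a CA1 marker, stood at 19.6 against 216 ± 14.9 CPM (-3.46, SE 0.11), and Nov at 10.4 against 177 ± 20.2 (-4.09, SE 0.16). Khdrbs3 was lower (78.8 against 140 ± 4.59 CPM, log2 fold change -0.83, SE 0.07), and Khdrbs1 (0.44, SE 0.06) and Khdrbs2 (0.47, SE 0.13) were higher. Counted over exons alone, Khdrbs2 stood at 12.6 against 4.40 CPM (log2 fold change 1.52, adjusted p = 1.5e-05). In the gene table it did not pass when only wild-type libraries were fitted (edgeR adjusted p = 0.0566). The knockout and dentate gyrus comparisons use the same 3 wild-type Ammon's horn libraries, so a shift in these would move both the same way. Of other nuclear genes named in the knockout, Slc16a8 (1.52), Card10 (1.02) and Cldn11 (-1.58) also differed in the same direction here. H2-Q2 (-0.23), Gm12816 (-0.24) and Rpl3-ps1 (-0.27) did not pass.

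Of 24486 genes tested, 5392 differed, 2733 higher and 2659 lower, of which 544 were higher and 430 lower by at least 2-fold. Other genes with the largest rises were Dsp, a desmosomal protein (3.52), Plk5 (3.42), Lct, the lactase gene (2.95), Pdyn, the prodynorphin gene (2.92), Calb2, the calretinin gene (2.87), and Npnt (2.81). The tRNA genes mt-Ty, mt-Tk, mt-Tq and mt-Tn were also higher (4.32, 3.41, 3.39 and 3.17); mt-Tk did not pass with DESeq2 or limma-voom (adjusted p = 0.0507 and 0.0912). Other genes with the largest falls were Ankrd63 (-4.58), Pou3f1 (-3.20), Lefty1 (-3.19), Nxph3 (-3.01), Htr5b, a serotonin receptor (-2.91), Mpped1 (-2.84), Spink8 (-2.84), Ptpru (-2.76), Dlk1 (-2.57) and Gpr161 (-2.46).

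Of 20 granule cell markers 18 were higher, 16 of them at least 2-fold, with 18 also when adjusted over the list alone (median 2.11), and Pdzd2 was lower (-0.43). All 11 CA1 markers were lower by at least 2-fold, and 11 adjusted over the list alone (median -2.46), among them Wfs1 (-1.57). Of 11 adult neurogenesis markers 6 were higher, Mki67 by 1.92, Neurod1 by 1.46 and Dcx by 0.59, and Sox4 was lower; adjusted over the list alone 7 were higher and 2 lower (median 0.94). Camera called the 3 lists (adjusted p = 2.7e-14, 6.8e-14 and 0.0256), and none with an estimated correlation (adjusted p = 0.267, 0.0832 and 0.546). The neurogenesis call also ended when genes needed 1 CPM in 3 libraries (median 0.59, adjusted p = 0.0862) and with exon-bin sums (0.0658).

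**Figure D4:**
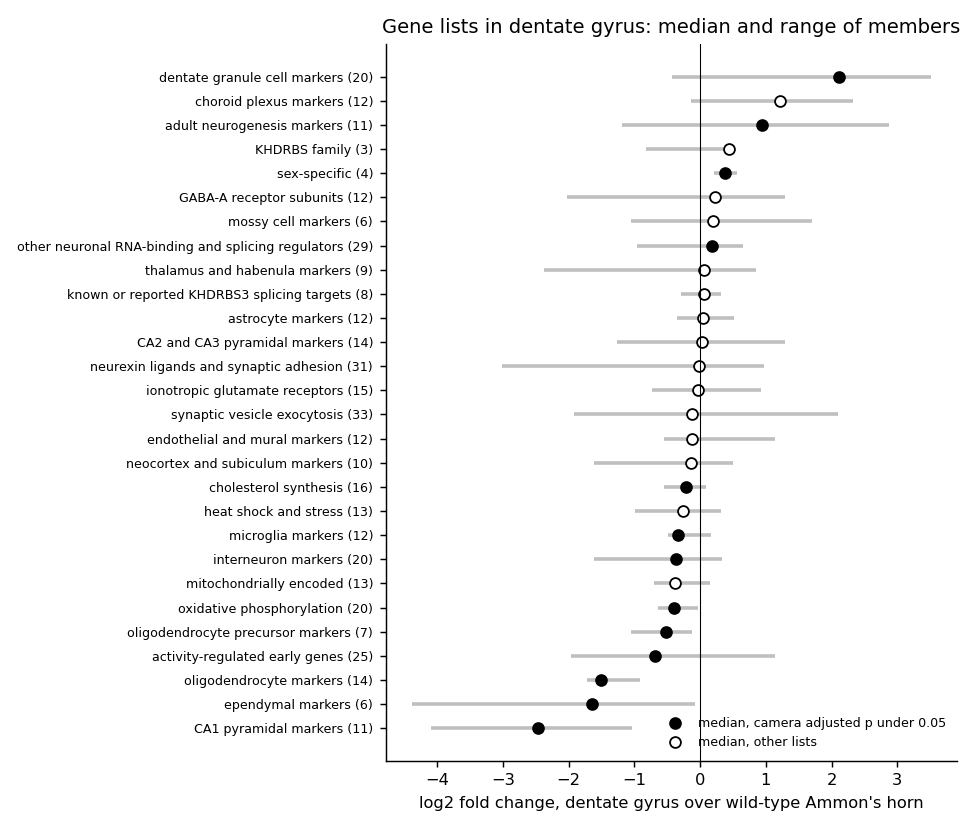
Log2 fold change, dentate gyrus over wild-type Ammon's horn (horizontal axis), for 28 gene lists (vertical axis), with the median of the members as a point and their range as a bar; filled points are lists called by camera. Granule cell markers have a median of 2.11, CA1 markers of -2.46 and oligodendrocyte markers of -1.50.

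All 14 oligodendrocyte markers were lower, 12 by at least 2-fold and 14 when adjusted over the list alone (median -1.50), with Mbp at -1.62 and Mobp at -1.71. Of 7 precursor markers 4 were lower, 5 adjusted over the list alone, with Sox10 at -1.05 and Olig1 at -0.90 (median -0.51). Of 6 ependymal markers 5 were lower, and 5 adjusted over the list alone, with Ccdc153 at -2.68 and Foxj1 at -1.25 (median -1.65). Of 20 interneuron markers 12 were lower and 2 higher, in the same numbers when adjusted over the list alone (median -0.36), with Pvalb at -1.61, Vip at -1.50, Sst at -1.12 and Reln at 0.34. Of 12 microglial markers 5 were lower, 7 adjusted over the list alone, with Tyrobp at -0.49 (median -0.33). Camera called these 5 lists (adjusted p = 2.7e-14, 0.0038, 7.4e-05, 1.5e-04 and 0.0040). None was called with an estimated correlation (adjusted p = 0.0832, 0.277, 0.260, 0.3003 and 0.267).

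Of 25 activity-regulated early genes 12 were lower, 7 of them at least 2-fold, and 3 higher (14 and 3 adjusted over the list alone, median -0.68). Dusp5 fell by 1.96 and Arc by 1.35 on the log2 scale, and Jun was higher (1.14). Of 20 oxidative phosphorylation genes 18 were lower, and 18 adjusted over the list alone (median -0.39, Ndufa1 -0.64). Of 16 cholesterol synthesis genes 6 were lower, 7 adjusted over the list alone (median -0.21, Fdft1 -0.55). Of 29 other splicing regulators 9 were higher and 4 lower, 12 and 4 adjusted over the list alone (median 0.18), with Tra2a at 0.66, Rbfox1 at 0.64 and Elavl4, a neuronal RNA-stability factor, at -0.96. Of 4 sex-specific genes 1 was higher, 3 adjusted over the list alone (median 0.38). Camera called these 5 lists (adjusted p = 0.0032, 2.9e-08, 0.0075, 0.0436 and 0.0498), and none with an estimated correlation (adjusted p = 0.546, 0.395, 0.546, 0.546 and 0.3003). The splicing regulator call ended without wild-type replicates 2 or 3 or knockout replicate 3 (adjusted p up to 0.0743), and the sex-specific call without wild-type replicates 1 or 3 or knockout replicates 2 or 3 (up to 0.0831). Both calls also ended with a filter of 1 CPM in 3 libraries (adjusted p = 0.0750 each) and with exon-bin sums (0.0584 and 0.151, where the sex-specific median was 0.25). The splicing regulator call ended with only wild-type libraries (0.0641), and the sex-specific call with DESeq2 (0.0711), RLE factors (0.0505) and no low-count filter (0.0738).

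The other 15 lists were not called, the smallest adjusted p being 0.0506 for mitochondrially encoded genes, of which 3 of 13 were lower (5 adjusted over the list alone, median -0.38). That list was called without knockout replicate 2 or 3 (adjusted p = 0.0064 and 0.0111), with DESeq2 (0.0400), limma-voom (0.0113) or no low-count filter (0.0409), and with only wild-type libraries (0.0030). Among GABA-A receptor subunits 5 of 12 were higher and 2 lower (6 and 2 adjusted over the list alone), with Gabra3 at -2.02, Gabrd at 1.29 and Gabra4 at 0.96. Among ionotropic glutamate receptors 4 of 15 were higher and 1 lower (7 and 2 adjusted over the list alone), with Grik2 at 0.92 and Grin3a at -0.73; the median was -0.03 while the test pointed up. Among synaptic vesicle exocytosis genes 7 of 33 were higher and 16 lower (9 and 16 adjusted over the list alone), with Stxbp6 at 2.10 and Cplx3 at -1.92. Among neurexin ligands and adhesion genes 3 of 31 were higher and 9 lower (3 and 11 adjusted over the list alone), with Cbln1 at -2.66, Lphn2 at -2.10 and Lrrtm4 at 0.97; the list was called without wild-type replicate 2 (adjusted p = 0.0482). Among CA2 and CA3 markers 3 of 14 were higher and 5 lower (4 and 5 adjusted over the list alone), with Coch at 1.29 and Nnat at -1.26.

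In the KHDRBS family 2 of 3 were higher and 1 lower, and adjusted over the list alone 2 and 1. Of 8 splicing-target genes 1 was lower, Nrxn3 (-0.28), and 0 adjusted over the list alone, with a median of 0.06 while the test pointed down. Among mossy cell markers 2 of 6 were higher and 1 lower (2 and 1 adjusted over the list alone), with Csf2rb2 at 1.71. Among astrocyte markers 1 of 12 was higher and 1 lower (3 and 1), and among endothelial and mural markers 1 of 12 was higher, Acta2 (1.13), and 3 lower (1 and 3), each pair in brackets being adjusted over the list alone. Thalamus and habenula markers had 1 of 9 higher and 2 lower (1 and 3 adjusted over the list alone), with Gpr151 at -2.38 and a median of 0.06 while the test pointed down. Neocortex and subiculum markers had 2 of 10 higher and 2 lower (2 and 2 adjusted over the list alone), with Fezf2 at -1.61. Heat shock and stress genes had 1 of 13 higher and 4 lower (1 and 5 adjusted over the list alone), with Cryab at -0.99, and were called with limma-voom (adjusted p = 0.0224). None of 12 choroid plexus markers passed, over all genes or over the list alone (median 1.21); that list was called without knockout replicate 2 (adjusted p = 0.0028) and with only wild-type libraries (0.0052).

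Exon usage also differed between regions. Bin 17 of Mbp, the myelin basic protein gene, took 6.09% of the gene's exon reads in the dentate gyrus (95% interval 5.83 to 6.36%) against 1.23% ± 0.0943 (SD, n = 3) in wild-type Ammon's horn, a usage log2 fold change of 2.32 (SE 0.11, edgeR adjusted p = 3.5e-35). Mbp had 12 called bins, and all 14 oligodendrocyte markers, Mbp among them, were lower in the dentate gyrus (median -1.50). Whether cell makeup accounts for this share was not tested. Bin 6 of Cxcl12, a chemokine gene (chromosome 6, 117173579 to 117175069), took 48.3% (46.4 to 50.2%) against 19.5% ± 1.08 (1.32, SE 0.12). Bin 17 of Il1rap, the interleukin-1 receptor accessory protein (chromosome 16, 26715069 to 26717744), took 5.06% (4.35 to 5.85%) against 18.1% ± 1.43 (-1.83, SE 0.15).

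In all, 360 of 169072 bins differed, 315 used more and 45 less, in 172 of 12270 genes. Other genes with the smallest p were Ndrg4 (bin 4, 1.46), Gpi1 (bin 11, 1.46), Aldoa (bin 16, 2.74), Cpne6 (bin 5, 1.66), Myo5b, a myosin (bin 24, 2.89), the joined Arhgef4 and C230030N03Rik (bin 2, 1.54) and Tiam2 (bin 4, -3.24), each value being a usage log2 fold change. The count was 196 without wild-type replicate 1 and 214 when bins needed at least 30 reads; limma-voom gave 553.

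Bin 44 of Nrxn2, used more in the knockout, was also used more in the dentate gyrus (3.66%, 95% interval 3.31 to 4.04%, log2 fold change 1.31, SE 0.14, edgeR adjusted p = 1.4e-12). The Nrxn3 bin that rose in the knockout had a value of 0.43 (SE 0.26) there and did not pass. A different bin of this gene passed, bin 31 (1.61, SE 0.32, adjusted p = 0.0019). Of 293 bins of the splicing-target genes, 3 were called over all bins and 4 when adjusted over the list alone. Best bins of Stxbp5l (0.39), Enpp2 (-1.48), Dgkb (-0.39), Kif21a (0.43) and Cask (-0.38) did not pass.

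Of the 5 bins called in the knockout, 4 (80%) had the same direction in the dentate gyrus, the exception being Apoe, and 1 was called there. Both comparisons share the 3 wild-type Ammon's horn libraries, and 100 simulations without any true change gave 95% ± 10 (SD) with the same direction. Bins with a true knockout change depend less on the shared libraries, so the simulated value does not apply to them directly. With only 5 bins, the share is no evidence for or against a common direction.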

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

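The fits without mitochondrial genes, with the choroid plexus covariate, without both choroid-rich knockout libraries and without Khdrbs3 in the count were chosen after the results were seen. Of the main results under their alternatives, 22 tests kept their direction and side of the threshold and 8 no longer passed. Of counts, 120 stayed within 1.5 times the reported one and 35 moved further, and of shares 10 lay within the exact 95% binomial interval of the reported one, which rests on 5 bins and is wide, and 1 lay outside. Of values of named genes, exon bins and lists, 1640 stayed the same, 108 no longer passed, 17 newly passed and 3 reversed. These tallies include the fit without both choroid-rich knockout libraries.

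The number of genes changed in the knockout (17, with 15 higher and 2 lower) was 117 with DESeq2 (73 higher, 44 lower), 10 with limma-voom (9 higher, 1 lower) and 8 with exon-bin sums (5 higher). It was 4 without mitochondrial genes (3 higher, 1 lower) and 26 with the choroid plexus covariate (7 lower). Without both choroid-rich knockout libraries 23 genes were higher. Leaving out 1 library gave 11 to 55 genes, 10 to 53 higher and 1 to 8 lower. Exon-bin sums change both the counting and the number of genes tested, and the cause was not tested for any of these.

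Khdrbs3 had a log2 fold change of 0.49 to 0.53 with 1 library left out. It was 0.54 without both choroid-rich libraries, where only 1 knockout library is left and is assumed to vary like the others. The number of lists called was 0 with an estimated correlation in both comparisons, against 7 in the knockout (6 to 8 with 1 library left out) and 13 in the dentate gyrus (11 to 14). The two-sided Fisher's exact p for genes near Khdrbs3 was 0.126 without Khdrbs3 itself (0.0310 in a window of 20 Mb), 0.195 without both choroid-rich libraries and 0.0037 to 0.142 with 1 library left out.

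The number of exon bins changed in the knockout (5, in 5 genes) was 8 in 8 genes when bins needed 1 read. With 1 library left out it was 5 to 8 bins in 5 to 8 genes. In the dentate gyrus 360 bins became 214 when bins needed 30 reads, 553 with limma-voom and 196 to 512 with 1 library left out. The share of knockout bins with the same direction there, 80%, was 100% when bins needed 30 reads, 62.5% when they needed 1 read and 60% to 87.5% with 1 library left out. The cause was not tested.

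Genes differing in the dentate gyrus numbered 4814 to 5346 with 1 library left out, with 496 to 536 higher and 401 to 464 lower by at least 2-fold. The 3 reversals were mt-Co1 (-0.40) and the median of mitochondrially encoded genes (-0.11) with exon-bin sums, and the median of choroid plexus markers without both choroid-rich libraries (-0.36). This last reversal follows from leaving out the libraries with high markers; for the others the cause was not tested. The Khdrbs3 bin could not be tested without a wild-type library, nor Apoe bin 18 at 30 reads. No paired analysis was possible because the replicate numbers only follow accession order. At this depth, 72% of simulated 1.5-fold changes in genes of at least 1 CPM were found in the knockout design and 34.3% in the dentate gyrus design.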

Other observations

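The explanations weighed in this part, and the values set against them, were chosen after the result was seen, except the 3 counts over other splits of the libraries. Some of these values come from fits that had been planned.

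Values of some ribosomal protein genes and of exon bins near the threshold were noted after the values were seen. Rpl3, a ribosomal protein gene on chromosome 15 (80077781 to 80083406), had a log2 fold change of -0.41 in the knockout and did not pass (edgeR adjusted p = 0.252), while its pseudogene Rpl3-ps1 rose by 0.65 and Rpl3-ps2 had a value of 0.50 (edgeR adjusted p = 0.158). Rpl3 and Rpl3-ps2 were called with the choroid plexus covariate. Exon bins that did not pass over all bins included bin 14 of Grik2, a kainate receptor (usage log2 fold change 0.78, adjusted p = 0.208), bin 9 of Tubg2 (-0.79, adjusted p = 0.228) and bin 6 of Tomm22 (-0.68, adjusted p = 0.170). The Grik2 and Tubg2 bins were called without wild-type replicate 2, and the Tomm22 bin when bins needed 1 read.

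Khdrbs1 and Khdrbs2 were higher in knockout Ammon's horn. Reads misplaced from the Khdrbs3 locus would gather in similar exons, yet the lowest fold of a Khdrbs2 exon bin was 3.66 and that of a Khdrbs1 bin with at least 100 reads in each library was 1.38. More dentate gyrus tissue in the knockout dissections would raise granule cell markers, whose median log2 fold change was -0.0052 and whose highest member, Glis3, reached 0.27. Khdrbs2 was called whichever library was left out, with a lowest log2 fold change of 0.77, but loss of KHDRBS3 cannot be told apart from other differences between the 2 groups, which would give the same.

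Of the 17 genes called in the knockout, 7 were mitochondrial, and each was higher in the gene table. For mt-Nd2 the gene table rose (log2 fold change 0.69) while the exon bins of mt-Nd2 and mt-Tw fell (-0.57). The part of the reads held by these bins thus differed between the genotypes, so they cannot tell whether there was more RNA. In its exon bins mt-Co2 had a value of 1.07, higher when adjusted over the list alone but not over all genes (edgeR adjusted p = 0.588). Alignments counted across gaps or repeats in the gene table may be the source, but no alignments were available to check this. Exon-bin reads made up 0.00585% of the gene-table reads of mt-Tl1, mt-Tq, mt-Tn and mt-Ty. Each of these genes had at most 3 exon-bin reads in any library of either genotype. That share therefore cannot tell why the gene table rose in the knockout. A role of the genotype cannot be told apart, because mt-Ty was also higher in the only wild-type dentate gyrus library (log2 fold change 4.32).

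Choroid plexus markers were high in 2 of the 3 knockout libraries. Choroid plexus tissue in some dissections may be the source, since the 12 markers moved together within groups (inter-gene correlation 0.959) and Ttr stood at 731 and 673 CPM in knockout replicates 1 and 3. A role of the genotype cannot be told apart with 3 libraries, since the lowest knockout library had a mean marker level of -0.60 (log2, relative to the wild-type mean) while the others lay above every wild-type Ammon's horn library.

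The 6 Ammon's horn libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 17 genes, 5 exon bins and 7 gene lists, and the highest other split gave 2, 4 and 4; in each case 1 split, the real one, gave as many.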
